A study of Mus musculus with 2 samples.

How the data were processed

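DNA methylation was measured by whole-genome bisulfite sequencing in 2 libraries of cultured mouse germ cells, 1 library per group. Bisulfite turns unmethylated cytosine into uracil, so a cytosine that survives is read as methylated. Libraries were made by post-bisulfite adaptor tagging (PBAT), in which adaptors are added after the bisulfite step, and sequenced on Illumina HiSeq instruments, per the labels' protocols. The d4c7 library came from primordial germ cell-like cells (PGCLCs) and the E9.5c5 library from primordial germ cells (PGCs) of E9.5 embryos, both expanded with cyclosporin A. The suffixes c7 and c5 were read as 7 and 5 days of culture.

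For each cytosine of a CpG the authors' files give raw counts of methylated and unmethylated reads, with no normalization. Per the submitters' processing notes, Trim Galore, Bismark 0.17.0 and SAMtools 1.3 were used with the mm10 genome build. Whether duplicate reads were removed was not given in the sources used here. The deposited counts cover 43735674 cytosines on 22 sequences in each library. No lambda phage sequence was among the listed sequences, so mitochondrial CpGs served as the background for incomplete conversion.

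The counts of the 2 strands of each CpG were added together, giving 21867550 CpGs on the 19 autosomes, X and Y. A CpG entered with at least 5 and at most 200 reads. A methylation level is the number of methylated reads divided by all reads over the CpGs of a region, in percent. Intervals are 95% Wilson binomial intervals. The labels name no molecular identifiers and 1 read can span several CpGs, so intervals cover counting error only and p-values are too small. With 1 library per group, each read test compares 2 libraries, not 2 conditions.

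The genome was divided into 2-kb tiles, and a tile was tested when at least 5 of its CpGs passed in both libraries. Read counts were compared by the two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the regions of a family. A region was called different at an adjusted p below 0.05 together with a difference of at least 10 percentage points. A tile was called retained at a level of 50% or more. Random lists, 10000 of each size, were matched to each gene list on deciles of the number of CpGs. A list's median level is given as its percentile among their medians.

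Gene positions came from an annotation of GRCm38.p6, the assembly behind mm10, used with no strand, exons or genome sequence. Promoters, which had been planned, were therefore replaced by the CpG-richer end of each protein-coding gene, from 1000 bp outside to 500 bp inside the gene, with at least 10 CpGs passing in both libraries. The richer end had at least 1.5 times the CpGs of the other end for 82.8% of the gene ends tested. With no strand, the end chosen can be either the start or the finish of a gene, so its level need not be a promoter level. Exons, introns, CpG islands and the windows at retroviral primer binding sites were planned but not analysed here. Of 17 imprinted regions, 14 were windows reaching 1000 bp to either side of the CpG-richer gene end. The other 3 lay upstream of H19 (2 to 4 kb), Meg3 (10 to 15 kb) and Rasgrf1 (28 to 32 kb), with gene strands taken from general knowledge. Nespas was found through its synonym Gnasas1. The annotated ends of Snrpn, Mest and Impact lie away from their textbook imprinted CpG islands.

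The 11 gene lists, the 17 regions, the thresholds and the rule for named genes were fixed before the data were examined. Among called gene ends with at least 100 reads in each library, the rule named the 10 with the largest difference in each direction. It also named the 10 gene ends with the highest lower level of the 2 libraries. In each list it named up to 4 members with the largest absolute difference and the member with the highest mean level. All imprinted regions, the 5 called tiles with the largest difference in each direction and the 5 longest runs of retained tiles could be named. Genes outside the rule are said to have been chosen after their values were seen.

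Read depth was compared in autosomal tiles as the depth per CpG relative to the autosomal median. Runs of at least 8 tiles with a depth ratio of 2 or more between the libraries were joined across gaps of up to 2 tiles, leaving out tiles under 0.25 in either library. The median tile stands for a run, and depths and levels of runs used every CpG, with no read limits. These settings were chosen after an exploratory scan.

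The Fisher test matched an independent implementation on 500 tables, and region sums matched direct sums in 300 regions. On binomial reads simulated at the real depths, 60% of tiles changed by 15 points were called, 72% at 20, 86% at 30 and 100% at 40, among 1053449 tiles. All 50 gene ends changed by each of these sizes were called among 18220, and no unchanged tile or gene end was called. The simulation held no correlation within reads.

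Alternatives covered the read minimum, single strands, equal mean depth, CpG spacing, tile size, gene-end windows, size thresholds and list matching, and 9 were added after the data were seen. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, numba 0.67.0, pyarrow 21.0.0 and matplotlib 3.10.9.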

Results

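The series examined whether cyclosporin A and FGF signalling support the growth and survival of mouse PGCLCs in culture, and the data described here are the methylomes of cells expanded with cyclosporin A. Cyclosporin A is an immunosuppressant that inhibits the phosphatase calcineurin. PGCLCs are germ cell precursors induced from embryonic stem cells through epiblast-like cells. The d4c7 library held PGCLCs of induction day 4 that had been cultured for 7 days, carried reporters for Blimp1 (Prdm1) and Stella (Dppa3), and were sorted for the Blimp1-mVenus signal. The E9.5c5 library held PGCs of E9.5 embryos cultured for 5 days and sorted for Stella-EGFP. Both cell types were grown on m220-5 feeder cells. Reads on CpGs numbered 382966606 in d4c7 and 307606392 in E9.5c5, with a mean depth of 17.5 and 14.1 reads per CpG. After the read limits, 84.1% and 82.3% of the 21867550 CpGs remained. There was 1 library per group, so no difference below has a replicate check.

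The 2 libraries were compared to ask how far genome-wide methylation had been lost in each cell type. Both genomes were almost free of CpG methylation. The level was 4.83% of reads in d4c7 (95% Wilson interval 4.82 to 4.83) and 4.06% in E9.5c5 (4.06 to 4.07). On the 17489557 CpGs that passed in both libraries, the level was 4.79% in d4c7 and 4.03% in E9.5c5. Each of the 19 autosomes was higher in d4c7, where autosomes ranged from 4.04% to 5.196% (SD over autosomes 0.275). In E9.5c5 they ranged from 3.24% to 4.66% (SD 0.317). Mitochondrial CpGs, the background for incomplete conversion, read as methylated in 0.533% of 1166298 reads in d4c7 and 0.485% of 913411 in E9.5c5. The difference between the libraries exceeded counting error, and its size relative to the spread between cultures is unknown.

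Chromosome X was more methylated than any autosome in both libraries, at 6.61% in d4c7 (6.59 to 6.63) and 5.39% in E9.5c5 (5.37 to 5.404). Chromosome Y stood at 17.2% (17.01 to 17.3) and 26.0% (25.6 to 26.4), on 21839 and 5118 CpGs. Depth per CpG relative to the autosomes was 0.358 in d4c7 and 0.533 in E9.5c5 on X, and 0.0317 and 0.0186 on Y. In E9.5c5, X depth was thus 1.49 times and Y depth 0.585 times that of d4c7.

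**Figure D1:**
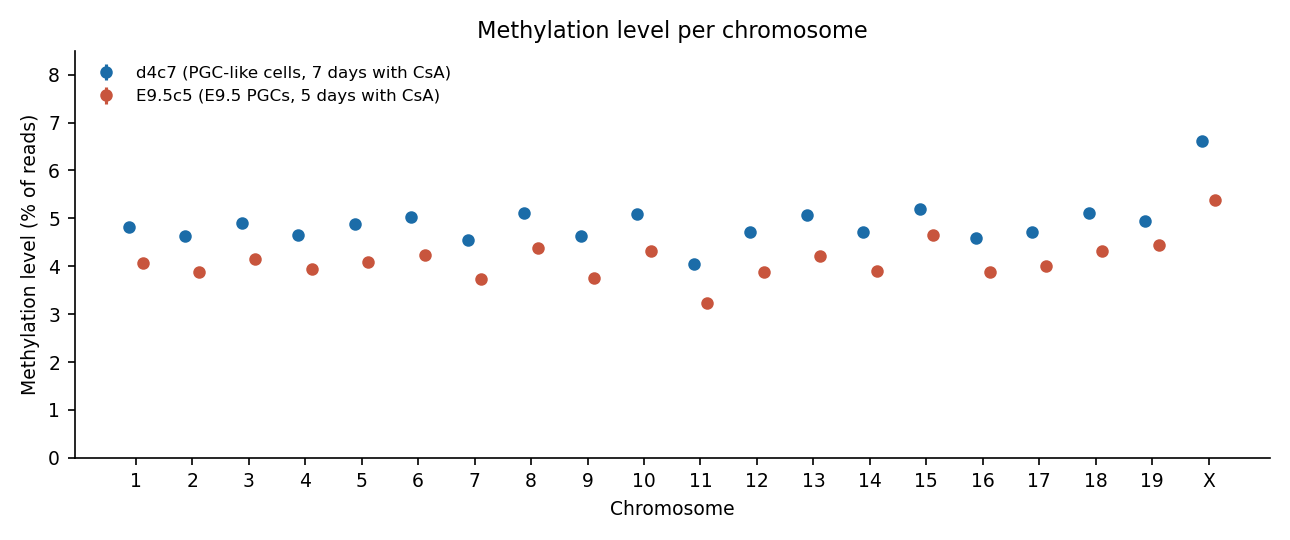
Methylation level (% of reads) per chromosome, 1 point per library and chromosome, for the 19 autosomes and X, with 95% Wilson intervals smaller than the points and Y left out. Every autosome lies higher in d4c7 (4.04% to 5.196%) than in E9.5c5 (3.24% to 4.66%), and X lies above the autosomes in both (6.61% and 5.39%).

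Among the CpGs within the read limits, the residual methylation was spread thinly. CpGs above 200 reads, left out here, held 8.83% of all reads in d4c7 and 9.10% in E9.5c5. Their levels were 21.3% and 17.4%, so part of the methylated reads lay on these 2829 and 2386 CpGs. CpGs at 0 to 20% made up 95.5% of the CpGs used in d4c7 and 96.2% in E9.5c5. CpGs at 80% or more made up 0.197% and 0.216%, or 36239 and 38885 CpGs. No methylated read was found at 54.7% and 64.9% of CpGs, a share that depends on depth. With the same number of reads drawn in both libraries at each CpG, an alternative added after the data were seen, it was 60.8% and 66.1%. Outside protein-coding genes the level was 5.72% in d4c7 and 4.88% in E9.5c5, and in gene bodies away from the CpG-richer end it was 4.32% and 3.52%. At the CpG-richer gene ends, taken in place of promoters, it was 1.56% in both libraries. The 706382 tiles with 5 to 19 CpGs had levels of 4.41% in d4c7 and 3.54% in E9.5c5. The 299140 tiles with 20 to 39 CpGs had 5.38% and 4.49%, and the 38488 tiles with 40 to 79 CpGs had 5.65% and 5.36%. In the 9439 tiles with 80 or more CpGs the order turned, with 1.40% in d4c7 (1.40 to 1.41) and 1.63% in E9.5c5 (1.62 to 1.63).

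**Figure D2:**
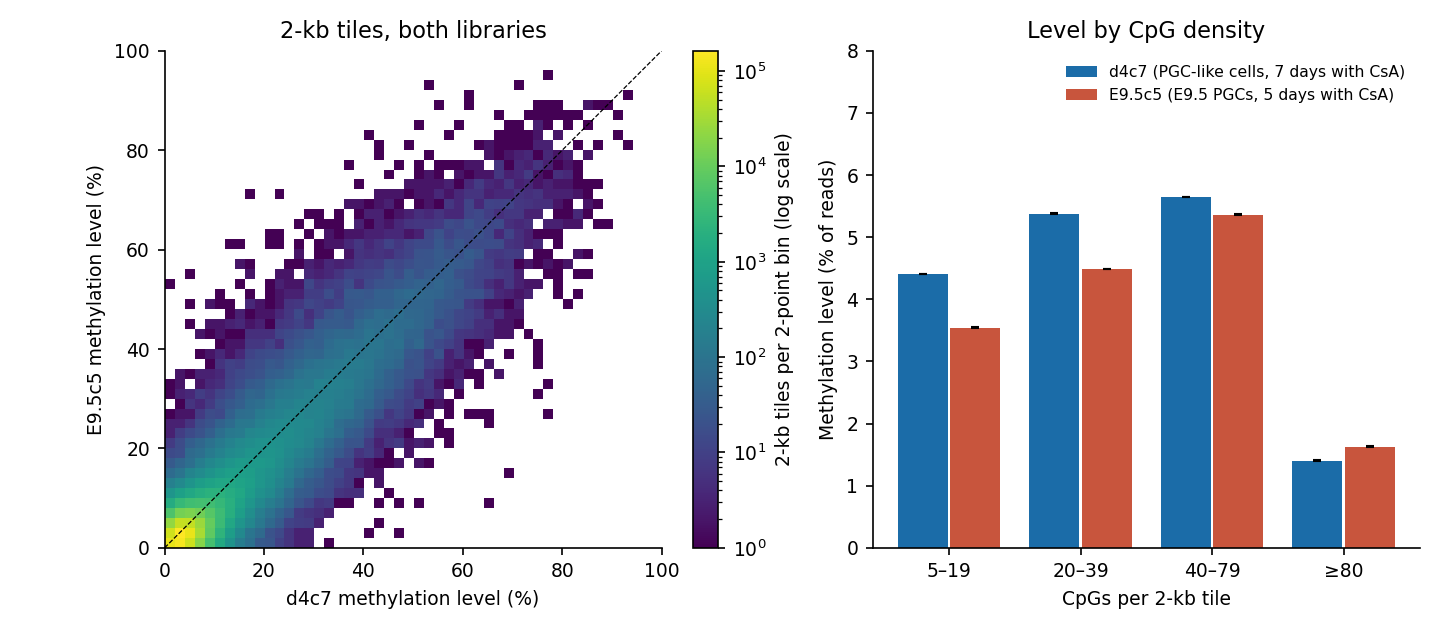
Left, methylation level (%) of 1053449 2-kb tiles in d4c7 (horizontal) against E9.5c5 (vertical), with colour giving the number of tiles per bin on a log scale and the dashed line equality. Right, level (% of reads) by CpGs per tile, bars with 95% Wilson intervals; d4c7 is higher at 5 to 19 CpGs (4.41% against 3.54%) and lower at 80 or more (1.40% against 1.63%).

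Tiles of 2 kb showed where the libraries differed. Of 1053449 tiles, 1685 were called higher in d4c7 and 1107 higher in E9.5c5. Without the size threshold, 14386 tiles were lower and 3376 higher in E9.5c5 at an adjusted p below the threshold. The median tile stood at 3.68% in d4c7 (quartiles 2.32 to 5.47) and 2.86% in E9.5c5 (1.65 to 4.50), with a median difference of -0.766 points (E9.5c5 minus d4c7). Tiles of 40 to 79 CpGs were called higher in E9.5c5 325 times and in d4c7 117 times. In tiles of 5 to 19 CpGs the counts were 312 and 953. The levels correlated across tiles with a Pearson's r of 0.873 and a Spearman's rho of 0.442, where tiles are not independent replicates. With a threshold of 20 points the balance turned to 274 higher in E9.5c5 and 206 in d4c7. Using CpGs at least 200 bp apart left 5 and 1, and as few reads drawn from all CpGs left 8 and 7.

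The called tiles with the largest differences were shallow and lay outside protein-coding genes. The tile at 11:92694001-92696000, 400805 bp from Car10, stood at 12.2% of 98 reads in d4c7 and 60% of 100 in E9.5c5. At 1:114808001-114810000, 874737 bp from Cntnap5a, the levels were 16.7% and 70.0%, on 54 and 50 reads. The other 3 called higher in E9.5c5 were nearest to Slc6a14, Sugct and Gm21317. The largest differences towards d4c7 were nearest to Cox7c (65.0% against 9.38%), Zscan4c (68.9% against 14.7%), Spin2f, Mme and Trib2. Called tiles with at least 500 reads in each library were chosen after their values were seen. Among them the largest difference towards E9.5c5 was at Y:90744001-90746000 within Gm52481. It stood at 26.3% of 688 reads in d4c7 and 59.7% of 797 in E9.5c5, on 26 CpGs. Chromosome Y had a mean depth of only 0.535 and 0.249 reads per CpG, so extra or misplaced reads are not excluded in this tile. Towards d4c7 the largest difference was at 1:182112001-182114000 within Gm39719 and Gm33725, with 50.4% of 1182 reads and 16.6% of 954. A tile at 6:33270001-33272000 within Exoc4, a subunit of the exocyst, stood at 17.96% in d4c7 and 50.3% in E9.5c5. A tile within H2-Eb1, which encodes a class II histocompatibility chain, at 17:34308001-34310000 stood at 18.5% in d4c7 and 2.49% in E9.5c5.

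Methylation of 50% or more was found in few tiles, and largely in the same ones. There were 3170 such tiles in d4c7 and 3084 in E9.5c5, of which 2104 were shared, where independent sets would share 9.28. They formed 1933 runs, of which 1769 were a single tile and the longest 3 tiles. The longest runs lay within S100a7l2 (3:91094001-91100000, 62.6% in d4c7 and 66.1% in E9.5c5), within Znrf3 (11:5360001-5366000, 56.2% and 63.1%), and nearest to Epc1 (18:6350001-6356000, 53.5% and 61.4%), Btbd35f2 and Fhit. Shared retained tiles lay on X in 8.79% of cases, against 3.72% of all tiles. The read limits passed 29.5% of the CpGs of these tiles, against 87.7% over all tiles tested. Of the tiles with at least 80% of their CpGs passing, an alternative added after the data were seen, 99 were retained in both.

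Few gene ends were called different between the libraries. Of 18220 tested, 23 were called higher in E9.5c5 and 15 higher in d4c7. Without the size threshold, 453 were higher in E9.5c5 and 374 in d4c7 at an adjusted p below the threshold. The median was 1.09% in d4c7 and 1.08% in E9.5c5. Among those higher in E9.5c5, the imprinted gene Zrsr1 stood at 3.58% in d4c7 (2.66 to 4.80) and 19.4% in E9.5c5 (16.9 to 22.2), at 11:22971005-22972504. The neutrophil chemokine gene Cxcl1 stood at 6.17% and 19.4%, Eps8l1 at 4.29% and 17.4%, the natural killer receptor gene Klrb1f at 27.5% and 45.2%, and the vomeronasal receptor gene Vmn2r79 at 10.9% and 27.8%. Tmem267 (13:119487086-119488585) had the largest difference, 31.6% of 1887 reads in d4c7 and 61.9% of 4558 in E9.5c5, the shallower library. It had 19.3 reads per CpG in d4c7 and 46.5 in E9.5c5, where the median gene end had 20.3 and 15.6. Gm52481 had 31.96 and 27.2 reads per CpG, while chromosome Y had a mean depth of 0.535 and 0.249. Gm52481 on Y, Ppp2r3d, Gm29986 and the ribosomal protein retrogene Rpl10l completed the 10. The imprinted neighbours Peg3 and Usp29, and Peg10 and Sgce, chosen after their values were seen, share their CpG-richer ends and were called too.

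Among the gene ends higher in d4c7, the clustered protocadherin gene Pcdha8 stood at 25.9% (22.9 to 29.2) against 5.89% in E9.5c5 (4.21 to 8.20), at 18:36991467-36992966. Ufsp2 and 1700029J07Rik, which share most of an end on chromosome 8, stood at 11.6% and 11.5% in d4c7 and at 0.722% and 0.254% in E9.5c5. Trim80 (27.3% and 16.1%), the macrophage scavenger receptor gene Marco (22.1% and 11.3%), the pore-forming gasdermin gene Gsdme (19.8% and 8.56%), Prr19, Cyp2d12, Gm9839 and Fscb were also higher in d4c7. Gdf3, named after its value was seen, stood at 11.7% in d4c7 and 1.20% in E9.5c5 and lies where read depth was unequal, as described for the reporter genes. Reads of the top strand alone turned the balance to 20 higher in E9.5c5 and 31 in d4c7. CpGs at least 200 bp apart left 2 and 1 calls.

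Gene ends that stayed methylated in both libraries were rare. A level of 10% or more in both was found at 249 gene ends, where independence would give 6.87, and 38 of these were on X. At 50% or more in both there were 4. Asmt, whose product completes melatonin synthesis, stood at 78.4% in d4c7 and 76.9% in E9.5c5 (X:170677555-170679054). Spin1 stood at 60.8% and 58.1%, the pregnancy-specific glycoprotein gene Psg23 at 56.3% and 62.0%, and Atp13a2, a lysosomal ATPase gene, at 51.6% and 53.3%. Rdh9, St6galnac1, Scgb1b3, Sec14l4, Sult2a4 and Cfap53 followed at 45.6% to 53.2% in d4c7 and 46.01% to 50.3% in E9.5c5.

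Germline genes, many of which are known to depend on promoter methylation for silencing, had the highest median level of the 11 gene lists. Their 38 gene ends had a median of 8.17% in d4c7 and 8.37% in E9.5c5, where matched random lists had 1.11% and 1.12%, at percentile 100 in both. Levels of 10% or more in both libraries were found at 11 of them. Rpl10l (16.2% against 30.1%) and Mael, a piRNA pathway gene (14.2% against 24.6%), were called higher in E9.5c5, none was called higher in d4c7, and the counts adjusted over the list alone were also 2 and 0. With the top strand alone both calls were lost, at differences of 7.83 and 6.10 points. Dpep3 was high in both (36.3% and 35.0%). Dazl, an RNA-binding regulator of germ cell development, stood at 22.2% in d4c7 (20.3 to 24.2) and 30.01% in E9.5c5 (27.6 to 32.6). The synaptonemal complex gene Sycp2 stood at 20.3% and 11.2%. Neither reached 10 points.

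**Figure D3:**
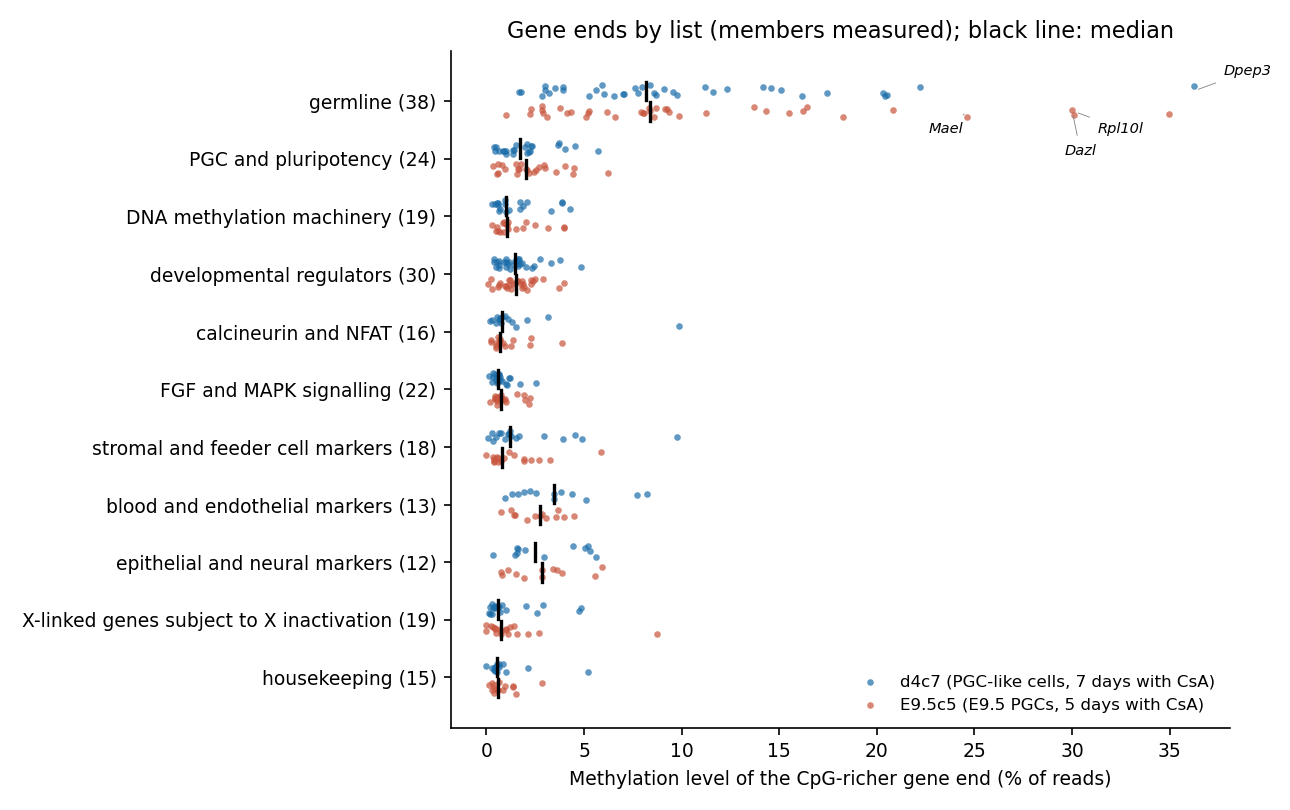
Methylation level (% of reads) of the CpG-richer gene end for the members of 11 gene lists, 1 point per gene and library, with the number measured in parentheses and black lines at the medians. Germline genes reach 36.3% (Dpep3 in d4c7) with medians of 8.17% and 8.37%, while the medians of the other lists lie between 0.527% (housekeeping, d4c7) and 3.44% (blood and endothelial, d4c7).

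The other 10 lists had no member called in either direction, also when adjusted over the list alone. PGC and pluripotency genes had medians of 1.74% in d4c7 (percentile 85.7) and 2.04% in E9.5c5 (percentile 96.9). In this list the germ cell factor gene Tfap2c stood at 0.432% and 2.96%, Pou5f1 at 2.33% and 4.51%, Dppa5a at 5.73% and 2.01%, and Tcl1 at 4.54% and 6.21%. Developmental regulators lay at percentile 100 in both libraries with medians of 1.44% and 1.51%, against 0.767% and 0.802% for random lists, and at percentiles 82.9 and 89.3 without matching on CpGs. Among them were Hoxd13 (0.653% and 3.97%), Neurog1 (0.655% and 2.91%), Cdx2 (2.73% and 0.586%), Gata4 and Foxa2. Genes of the methylation machinery had medians of 0.987% and 1.07% (percentiles 59.8 and 69.5), with Dnmt1 at 3.89% and 3.97%, Tet1 at 1.17% and 3.95%, Uhrf1 at 1.72% and 0.466%, and Dnmt3a at 3.87% and 1.52%. The differences at Pou5f1, Dppa5a, Tcl1, Dnmt1, Uhrf1 and Dnmt3a did not reach an adjusted p below 0.05. For any single gene named here, the CpG-richer end may lie at the finish of the gene, so these are not promoter levels.

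Of the pathways named in the series title, calcineurin and NFAT genes had medians of 0.786% in d4c7 and 0.699% in E9.5c5 (percentiles 50.0 and 18.97). The testis calcineurin subunit gene Ppp3r2 stood at 9.88% (7.76 to 12.5) and 2.31% (1.29 to 4.08). FGF and MAPK genes had medians of 0.609% and 0.744% (percentiles 15.1 and 57.5), with Fgf8 at 2.53% and 0.740% and Fgf9 at 0.110% and 1.57%. The mitochondrial background was 0.533% in d4c7 and 0.485% in E9.5c5. The medians of these lists lie close to it, as do those of X-linked and housekeeping genes, and Fgf9 in d4c7 lies below it. Stromal and feeder cell markers had 1.19% and 0.814% (percentiles 34.7 and 5.30), with Lum at 9.74% and 5.88%. Blood and endothelial markers had 3.44% and 2.76% (81.6 and 80.9), with Gata1 at 8.24% and 2.76%. Epithelial and neural markers had 2.47% and 2.84% (98.3 and 99.5), with Krt18 at 1.59% and 5.91%. X-linked genes subject to X inactivation had 0.565% and 0.7505% (1.29 and 17.8), with Hprt at 0.674% and 2.69%. Housekeeping genes had 0.527% and 0.585% (1.16 and 4.13), with Actb at 5.21% and 2.85%. The differences at Lum, Gata1, Hprt and Actb did not reach an adjusted p below 0.05. In d4c7 the percentile of epithelial and neural markers was 95.7 without matching, and that of housekeeping genes was 4.01 with a minimum of 10 reads, both within the central 95%.

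Imprinted regions, methylated on 1 parental copy in somatic cells, were at 33.1% or less in the fixed windows of both libraries, and those called different were higher in E9.5c5. Kcnq1ot1 stood at 12.2% in d4c7 (10.7 to 13.8) and 24.6% in E9.5c5 (22.4 to 27.0), Peg10 at 19.7% (18.1 to 21.4) and 33.1% (30.7 to 35.5), and Zrsr1 at 5.70% (4.84 to 6.70) and 17.5% (15.8 to 19.3). These 3 of 17 regions were called higher in E9.5c5 by Fisher's exact test, with adjusted p of 3.87e-15, 9.52e-17 and 9.80e-31. None was called higher in d4c7, and the counts adjusted over the list alone were also 3 and 0. The median region stood at 5.87% in d4c7 and 10.0% in E9.5c5, and 14 of 17 were higher in E9.5c5.

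Another 5 regions passed the adjusted p without reaching 10 points. These were Peg3 (16.7% and 25.8%), Gnasas1 (6.88% and 16.1%), Airn (6.09% and 12.0%), and the paternally methylated regions upstream of Rasgrf1 (4.03% and 12.5%) and H19 (5.87% and 9.26%). The region between Dlk1 and Meg3, also paternal, stood at 8.59% and 10.0%. Peg13 stood at 9.53% and 11.9%, Nnat at 7.09% and 7.74%, Mcts2 at 5.61% and 6.96%, Plagl1 at 3.02% and 4.36%, and Nap1l5 at 4.18% and 3.98%. Mest (5.22% and 4.199%), Impact (3.73% and 2.72%) and Snrpn (1.45% of 69 reads and 5.71% of 70) were measured away from their known CpG islands. In the tile with most CpGs of each gene, added after the data were seen, Impact stood at 14.2% and 24.3% and Mest at 16.2% and 24.3%. The tile of Airn (17:12768001-12770000) lay outside its fixed window (17:12740311-12742310). It stood at 2.19% (1.66 to 2.88) in d4c7 and 0.387% (0.188 to 0.797) in E9.5c5. The tile of Snrpn, also outside its window, stood at 67.9% of 28 reads and 55.9% of 34, on 4 of 75 CpGs. In these tiles Peg10 and Zrsr1 fell short of 10 points, at 7.80 and 9.25 points, as they did on the top strand alone, at 9.42 and 7.04 points. Peg3 and Gnasas1 differed by 3.96 and 0.898 points in these tiles. The tiles of Peg10, Zrsr1 and Peg3 overlapped their fixed windows only in part, so their values cover partly other sequence. At Peg10 the tile was 6:4748001-4750000 and the window 6:4746306-4748305. The tile of Gnasas1 (2:174284001-174286000) lay outside its fixed window (2:174294437-174296436), so it does not test the difference found there.

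**Figure D4:**
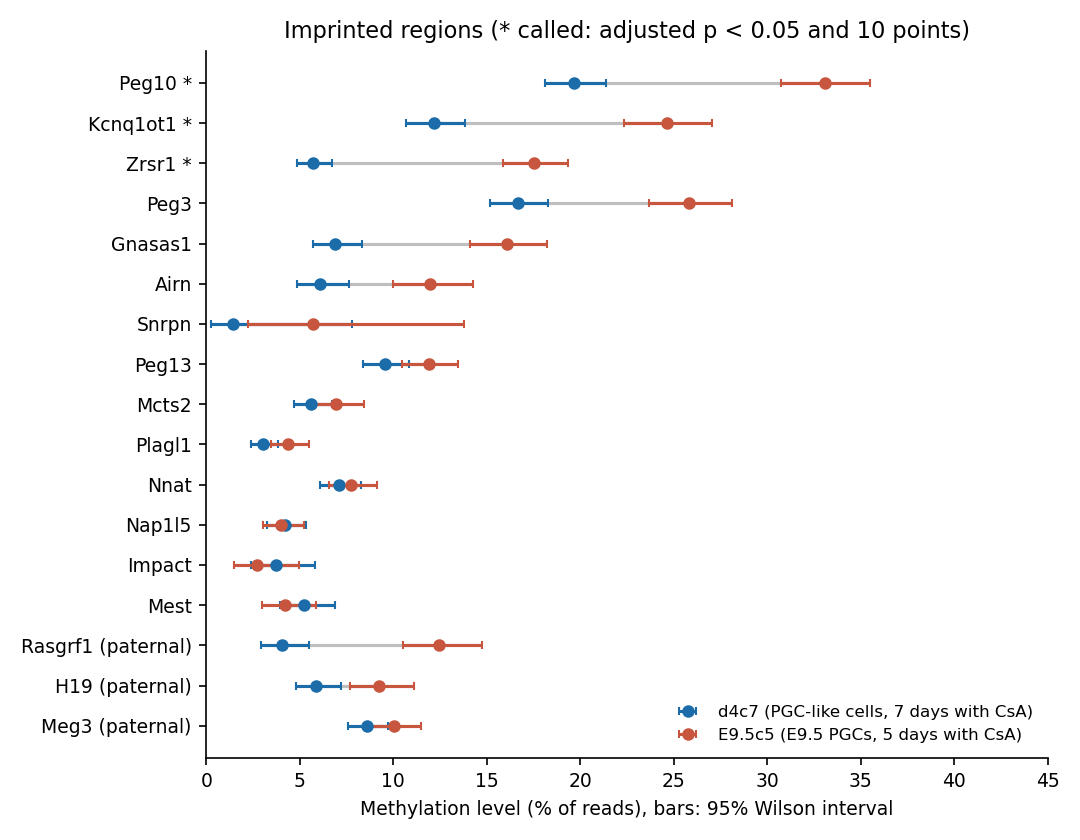
Methylation level (% of reads) of 17 imprinted regions, 1 point per library with its 95% Wilson interval, grey lines joining the libraries, and asterisks at called regions. E9.5c5 lies to the right in 14 regions, most at Peg10 (33.1% against 19.7%), Kcnq1ot1 (24.6% against 12.2%) and Zrsr1 (17.5% against 5.70%).

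Both libraries carried reporters according to the labels, and read depth at the reporter genes was unequal. Over 230 kb around Prdm1 (10:44370001-44600000), the median tile had 5.67 times the autosomal median depth in d4c7 and 1.19 times in E9.5c5. At Dppa3 and the end of its neighbour Gdf3 (6:122610001-122630000) it was 19.2 times in d4c7 and 4.005 times in E9.5c5. The flanks were deeper in E9.5c5, at 4.46 against 1.28 times over Apobec1 and Gdf3 (6:122568001-122610000), and at 2.89 against 1.03 times beyond Dppa3 (6:122630001-122646000). Without read limits, in the 2 tiles that overlap Dppa3, 16.3% of 32917 reads were methylated in d4c7 (15.9 to 16.7) and 1.29% of 5363 in E9.5c5 (1.02 to 1.62). The other 7 tiles of that run stood at 4.47% and 2.03%, and the run at Prdm1 at 4.09% and 2.95%. With the limits, the tile at 6:122628001-122630000 kept 16 of 38 CpGs and stood at 22.3% of 2139 reads in d4c7 and 2.01% of 746 in E9.5c5. Depth was thus in excess at Dppa3 in both libraries and at Prdm1 in d4c7.

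**Figure D5:**
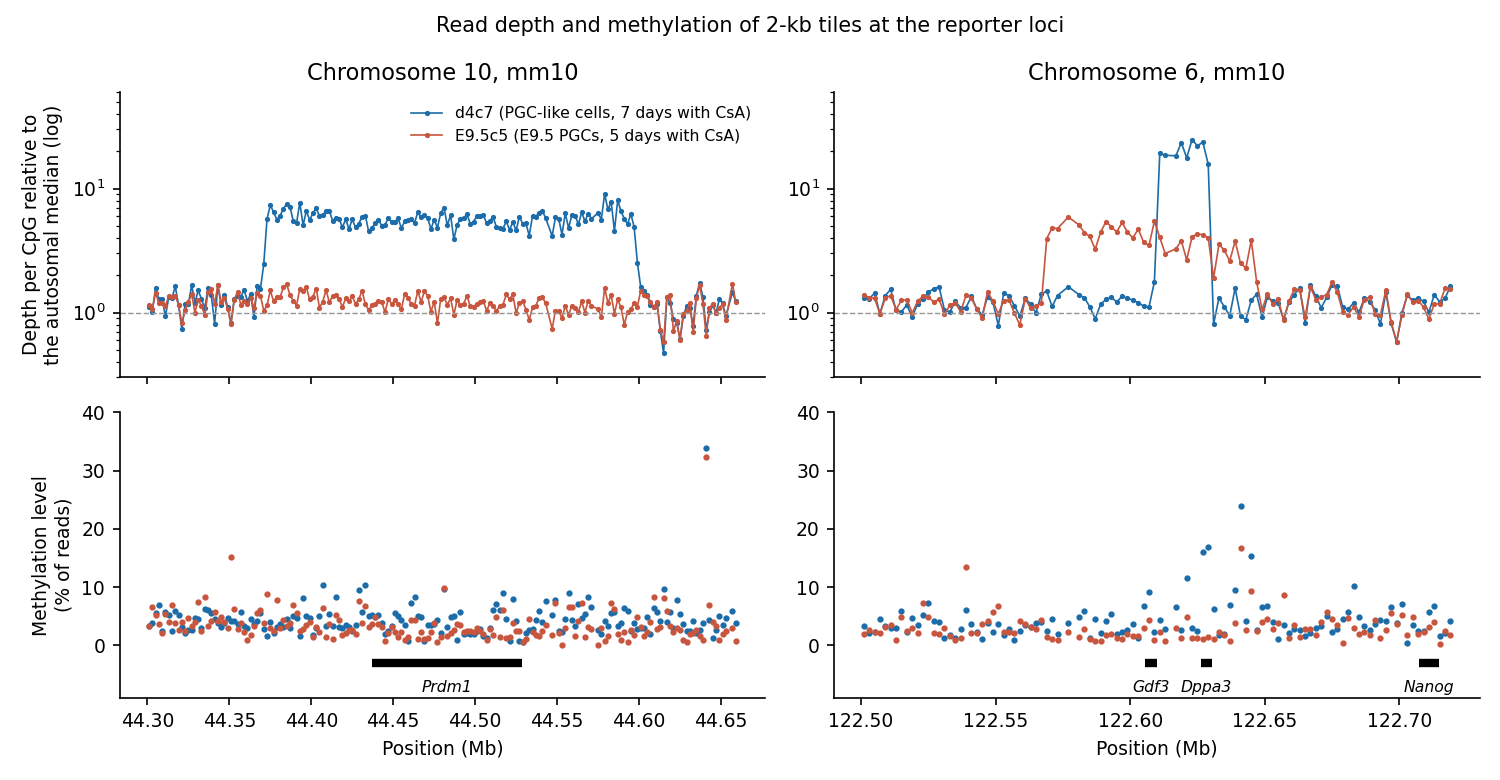
Read depth per CpG relative to the autosomal median (top, log scale) and methylation level in % of reads (bottom) of 2-kb tiles along chromosomes 10 and 6 (Mb, mm10), 1 point per tile and library, with genes as black bars. In d4c7 the median tile lies at 5.67 times in the 230-kb run at Prdm1 and at 19.2 times in the run at Dppa3, against 1.19 and 4.005 times in E9.5c5.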

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

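The settings for runs of unequal depth and the 4 tests on them were chosen after the result was seen. The exploratory scan had also shown runs of at most 3 tiles elsewhere.

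CpGs above 200 reads were left out by the read limits and carried more methylation than the CpGs used. They enter the values of the depth runs and the setting with no maximum of reads. There were 2829 in d4c7 with 8.83% of all reads and a level of 21.3%, and 2386 in E9.5c5 with 9.10% of reads and a level of 17.4%. Chromosome 2 held 74.96% and 75.5% of these reads and chromosome 9 14.5% and 14.8%.

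Read depth departed from the rest of the genome in 4 long autosomal runs. In the median tile it was 5.67 times the autosomal median in d4c7 at Prdm1 (10:44370001-44600000) and 19.2 times in d4c7 at Dppa3 (6:122610001-122630000). In E9.5c5 it was 4.46 times at 6:122568001-122610000, over Apobec1 and Gdf3, and 2.89 times at 6:122630001-122646000, beyond Dppa3.

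Uneven amplification or mapping would raise the depth at Prdm1 in both libraries, yet in E9.5c5 it was 1.19 times the median, within the central 95% of autosomal tiles, as d4c7 was in the flanks of Dppa3 at 1.28 and 1.03 times. At Dppa3 the ratio was 4.805 towards d4c7 while E9.5c5 was deeper in both flanks, against this as the whole cause; both libraries were deep in the run at Dppa3, so a share of it stays open there. DBA/2 was assumed at 1 copy in 2 in d4c7 and 1 in 4 in E9.5c5. Copy number that differs between C57BL/6 and DBA/2 then allows a ratio of at most 2, and the ratio at Prdm1 was 4.75. All 4 long runs lay at or beside Prdm1 or Dppa3, the genes of the labelled reporters. A candidate explanation is that copies of the reporter transgenes add these reads, with the Blimp1 reporter named for d4c7 alone, in which case the 16.3% at Dppa3 in d4c7 may mix the endogenous gene with transgene copies, which these reads cannot separate; no biological explanation was tested.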

How the results depend on the processing

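No paired analysis was possible because each group holds 1 library. For the same reason leaving out a library was impossible. The alternatives for the retroviral primer binding sites were not run. The settings on the covered share of CpGs, the richer gene end, autosomal regions, the runs of unequal depth, the same depth at each CpG and the densest tile were chosen after the data were seen. Where no reason is given, the cause was not tested.

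All 10 settings kept the global level lower in E9.5c5, by differences of -0.721 to -0.999 points. The levels in d4c7 and E9.5c5 were 4.86% and 4.11% with a minimum of 1 read, 4.75% and 3.96% with 10 reads, 4.99% and 4.23% on the top strand, and 4.67% and 3.92% on the bottom strand. They were 5.04% and 4.24% as the mean of CpG levels, 4.79% and 4.03% on autosomes, 4.79% and 4.03% on CpGs passing in both, 6.29% and 5.29% with no maximum of reads, and 4.32% and 3.596% after subtracting the background. With d4c7 thinned to the mean depth of E9.5c5 its level was 4.81%.

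Tiles called higher in E9.5c5 numbered 728 with a minimum of 10 reads and 629 on the bottom strand. Tiles higher in E9.5c5 and in d4c7 numbered 2132 and 8486 at 5 points, 274 and 206 at 20 points, 663 and 844 with tiles of 5 kb, and 5 and 1 with CpGs 200 bp apart. Tiles of 1 kb gave 2938 higher in d4c7. Gene ends higher in E9.5c5 and in d4c7 numbered 59 and 114 at 5 points, 2 and 1 at 20 points, and 2 and 1 with CpGs 200 bp apart. Those higher in d4c7 numbered 9 with a minimum of 10 reads and 31 on the top strand. Spacing left 94 reads per tile in place of 233, and as many reads drawn from all CpGs called 8 and 7 tiles and 1 and 0 gene ends. Almost nothing could be called at this depth either way. The setting therefore cannot tell fewer reads from the removal of correlation within reads. Of 21 called gene ends named by the rule, 2 passed in every setting run on them, Tmem267 and Gm52481, and none turned direction. Their depth was unusual, at 46.5 reads per CpG for Tmem267 in E9.5c5 and 31.96 and 27.2 for Gm52481, above the central 95% of gene ends (up to 27.8 in d4c7 and 21.5 in E9.5c5), so passing every setting does not exclude extra or misplaced reads.

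Retained tiles shared by both libraries numbered 11568 at 30%, 154 at 70%, and 99 with 80% of CpGs passing. Imprinted regions higher in E9.5c5 numbered 2 to 5 over 7 settings, with 5 for windows of 500 bp to either side, none higher in d4c7, and 14 to 16 with a difference above 0. Impact turned to 10.1 points higher in E9.5c5 in its densest tile, another part of the gene. Airn, not called in either, stood at -1.80 points in its own, which also lies outside its fixed window. Across tiles r was 0.877 and rho 0.446 with a minimum of 10 reads, and 0.895 and 0.475 in tiles of 100 reads.

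List percentiles crossed the central 95% in 14 of 66 values. With a minimum of 10 reads, PGC and pluripotency genes lay at 98.1 in E9.5c5 and housekeeping genes at 4.01 in d4c7 and 1.25 in E9.5c5. For gene ends with 1.5 times the CpGs of the other end, PGC and pluripotency genes lay at 97.9 in E9.5c5, epithelial and neural markers at 89.9 in d4c7, and housekeeping genes at 3.35 in d4c7. Without matching on CpGs, d4c7 and E9.5c5 percentiles were 82.9 and 89.3 for developmental regulators and 99.6 and 99.2 for blood and endothelial markers. Unmatched lists also gave 98.1 for PGC and pluripotency genes in E9.5c5, 0.52 for FGF and MAPK genes in d4c7, 95.7 for epithelial and neural markers in d4c7, and 0.99 for housekeeping genes in E9.5c5. The median tile held 233 and 190 reads.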

Other observations

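The gene families here, and the tests of cell mixtures and of incomplete conversion, were chosen only after the results were seen. Of 14 families picked by symbol, the pregnancy-specific glycoprotein genes stood highest, with 5 gene ends at a median of 21.3% in d4c7 and 18.7% in E9.5c5. Psg23 (56.3% and 62.0%), Psg29 (30.3% and 24.4%) and Psg28 (21.3% and 18.7%) led them, and Psg16 stood at 1.66% and 2.64%. The type 2 vomeronasal receptor genes (Vmn2r, 6 gene ends) had medians of 11.5% and 16.04%, where matched random lists had 3.16% and 2.40%. Olfactory receptor genes (Olfr, 288 gene ends) had 4.54% and 3.06%, against 3.42% and 2.63%, and keratin genes (Krt, 53 gene ends) 4.95% and 3.55%, against 2.64% and 2.16%.

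Zinc finger genes (Zfp, 359 gene ends) lay at the bottom of their random lists, at 0.858% in d4c7 and 0.982% in E9.5c5 against 1.20% in both. The 38 Hox gene ends stood at 1.52% and 1.55%, against 0.844% and 0.884%. The beta protocadherin genes (Pcdhb, 22 gene ends) lay at percentile 11.1 in d4c7 and 99.0 in E9.5c5, with medians of 2.62% and 3.79% and no member called. For the other families, the percentiles in d4c7 and E9.5c5 were 99.2 and 98.97 for Vmn1r, 94.1 and 99.98 for Rhox, 95.4 and 99.8 for Pcdha, and 99.9 and 90.6 for Pcdhg. They were 98.1 and 100 for Cyp, 89.5 and 93.0 for Serpin, and 43.8 and 22.4 for Ugt genes. Among gene ends at 10% or more in both libraries, 15.3% lay on X, against 3.44% of all gene ends, and no explanation for the level of X was tested.

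The lower genome-wide level in E9.5c5 was weighed against 3 technical explanations. Incomplete conversion in d4c7 as the whole cause would raise tiles of every CpG density, yet in tiles of 80 or more CpGs E9.5c5 was 0.227 points higher. With d4c7 thinned to the mean depth of E9.5c5 the difference kept 0.980 of its size. Random thinning keeps the expected level of each CpG, so it shows only that the read minimum mattered little and does not decide on depth. Feeder cells in d4c7 would make germline gene ends higher in d4c7. These ends moved both ways (median 0.376 points, quartiles -1.37 to 1.31, 21 above and 17 below 0). Their median difference lay towards E9.5c5, at percentile 99.77 of matched random lists (random median -0.0265 points), opposite to that prediction. Feeder cells remain open, since single members went both ways and each group holds 1 library, although the mVenus sort would remove such cells. The origin of the cells and the days in culture differ between the libraries too and may account for the difference, which 1 library per group leaves untested.

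The higher levels of imprinted regions in E9.5c5, in the fixed windows, were weighed in the same way. Somatic or feeder cells in E9.5c5 would raise methylation across the genome, while the median tile differed by -0.766 points and the whole library stood at 4.06%. The d4c7 library is no reference for pure E9.5 germ cells, so a share of such cells stays open, although the Stella-EGFP sort would remove them. The level of 4.06% limits that share, and whether it could give differences of this size was not tested. Strain variants that remove single CpGs on DBA/2 copies would leave most CpGs unchanged. In the 3 called regions, 79.9% of the 274 CpGs were higher in E9.5c5 (95% interval 74.8 to 84.2), so the difference was spread over many CpGs. The regions were picked for that difference in the same reads, which raises the share. Neighbouring CpGs share reads, so the interval is too narrow. With d4c7 thinned to the mean depth of E9.5c5, 3 regions were called. Random thinning keeps the expected level, so this shows only that the calls did not need the extra d4c7 reads. A hypothesis that stays open is that imprinted methylation may be lost to different degrees in cells from embryos and from stem cells, or over 5 and 7 days of culture. The share of DBA/2 copies and the depth of X and Y differ as well, and this design separates none of these.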
